A study of Homo sapiens with 24 samples.

How the data were processed

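Poly(A)-selected RNA from MV4-11 cells was sequenced with unstranded libraries and reads of 101 bases, per the labels. The deposited files comprised a gene table and a transcript table, each with 24 libraries as columns. As deposited, the values of both tables were estimated counts (expected_counts) per gene or per transcript, not scaled between libraries. This unit was read from the values, many of which were not whole numbers, since the authors did not state it. The library totals were equal between the tables and ran from 32.5e6 to 61.1e6. The submitters' processing notes named Salmon 1.2.1, STAR 2.7.3a, R 4.0.0, DESeq2 1.28.1 and the GRCh38 genome build without saying in which order or for which table each was used. The annotation release, any filter and any correction for transcript length were not stated.

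The libraries formed 8 groups of 3, with replicates A, B and C: DMSO, PRT220, GSK-LSD1, PRT220 with GSK-LSD1, MS023, MS023 with GSK-LSD1, MC4455 and MC4491. The labels did not say whether replicates came from separate cultures, so p-values measure only the spread between these samples. No column of the tables was left out. Pairs of libraries of the same group were checked for duplicates, and 0 of 24 pairs were identical.

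Estimated gene counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, with TMM scaling, the filterByExpr filter and all 24 libraries in 1 fit with 1 coefficient per group. Of 38048 genes in the table, of which 29718 had a symbol, 16640 passed the filter. A gene was called at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and "adjusted p" without another name refers to this test. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are given as CPM, counts per 1e6 counts, after TMM scaling, as mean ± SD with n = 3 per group. There were 14 comparisons: 7 treatments against DMSO, each combination against its single agents, the interaction of each combination (combination minus both single agents plus DMSO on the log2 scale), and MC4455 against MC4491.

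Named genes followed a rule. For PRT220, GSK-LSD1 and their combination against DMSO and for the interaction of PRT220 with GSK-LSD1, these were the 10 largest log2 fold changes in each direction among called genes with a symbol, a mean of at least 5 CPM in the higher group, and every library of one group above every library of the other. In an interaction the last condition was asked of the combination against at least 1 single agent. Other comparisons took 5 per direction, and each gene list up to 4 called members with the largest change, or up to 2 members with the highest mean CPM where none was called. PRMT5, KDM1A, PRMT1, MYC, CDKN1A, MDM4, ITGAM, CD86 and GFI1 were always taken. The text uses fewer than the rule gives, and genes with near-identical copies or readthrough models are left out or marked uncertain.

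The 25 gene lists covered markers of monocytes and macrophages, granulocyte and granule genes, the LSD1-CoREST-GFI1 complex, MLL-fusion target genes, stem and progenitor markers, MYC and ribosome biogenesis genes, S phase genes, G2 and M phase genes, p53 target genes, interferon-stimulated genes, antigen presentation genes, NF-kB and inflammatory genes, the BCL2 family, ATF4 and amino acid response genes, endoplasmic reticulum chaperones, cholesterol synthesis genes, arginine methyltransferases and cofactors, splicing factors and snRNP proteins, DNA repair genes, and MAPK and STAT5 feedback genes. Lists for other cell types or RNA quality covered erythroid and megakaryocyte markers, neuronal genes repressed by REST-CoREST, T, NK and B lymphocyte markers, epithelial and fibroblast markers, and mitochondrial transcripts. Each list was tested against the other genes with camera in limma 3.58.1 at a preset correlation of 0.01 and with at least 5 tested members, with Benjamini-Hochberg adjustment within a comparison, and again with a correlation estimated from the data. Calls were also counted with the p-values adjusted over the list alone.

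Transcripts were paired with genes by identifier through GENCODE 29, which may not be the release behind the deposited tables. The pairing covered 167008 of 178398 transcripts and between 96.6% and 96.8% of the reads of each library. Transcript usage was tested with limma's voom and diffSplice on 74393 transcripts of 11428 genes with at least 2 kept transcripts, with Simes p-values per gene and Benjamini-Hochberg adjustment. The share of paired reads on transcripts annotated as retained introns was compared with a two-sided exact permutation test, whose smallest p with 3 against 3 libraries is 0.1. Fold changes of the 7 treatments against DMSO were correlated across genes in 21 pairs. Because the DMSO libraries were shared, unchanged groups against the same controls were simulated.

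The groups, tests, lists, naming rule and alternative settings were fixed before the data were examined. These settings were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors in place of TMM, no filter, a filter of at least 1 CPM in at least 3 libraries, a fit of the compared groups alone, the replicate letter as a block, a log2 fold change of at least 1, and each library left out in turn. For lists, estimated correlations and both forms of fry were planned. For transcript usage, edgeR's diffSpliceDGE was planned. For the correlations, a mean of at least 5 CPM, a prior count of 5 in place of 0.125, and fits without each DMSO library were planned. Chosen after seeing the data were a term for the 8 libraries with under 5 CPM of RRP9, and fits of the 8 such libraries or the other 16 alone. Other splits of the same libraries into groups of the same sizes were counted, all 10 for a pair of groups and 50 random ones for an interaction.

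The tests were run on simulated data with known changes. Of 100 genes changed 1.5-fold in a simulated PRT220 comparison, 56% were called, against 77% of 100 genes changed 2-fold, with 7 false calls among 16472 genes. In a simulated interaction the shares were 39% and 66%, with 7 false calls among 16464 genes. The list test found the changed list and 0 other lists of 25. The usage test found 89.5% of 190 changed genes, with 11 false calls among 10826 genes. Its simulated transcripts varied independently with 1 common dispersion, which is simpler than real transcript estimates. In the real libraries every regrouping of treated and DMSO libraries still called at least 244 genes. The 11 false calls therefore do not show how many false calls the real counts hold. Results for some genes are not reported.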

Results

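Gene and transcript levels were measured by poly(A) RNA sequencing in MV4-11, an established human acute myeloid leukaemia cell line that carries the MLL-AF4 fusion. The 24 libraries formed 8 groups with 3 libraries each. Cells received DMSO as the control, PRT220 (a PRMT5 inhibitor, 3 nM), GSK-LSD1 (an LSD1 inhibitor, 10 nM) or both for 3 days. The other groups received MS023 (an inhibitor of type I arginine methyltransferases), MS023 with GSK-LSD1, MC4455 or MC4491, for which the labels gave neither dose nor time. PRMT5 is the main enzyme for symmetric dimethylation of arginine, and LSD1, encoded by KDM1A, removes methyl groups from histone H3 and serves the GFI1 repressors in myeloid cells. Per library, the gene table held 32.5e6 (MC4455 C) to 61.1e6 (DMSO B) estimated counts. The tests covered 16640 genes, and coordinates refer to GRCh38. KDM1A (ENSG00000004487, chromosome 1, 23019443 to 23083689) had a log2 fold change of -0.05 with PRT220 and fell by 0.24 on the log2 scale with the PRT220 combination, and PRMT5 (ENSG00000100462, chromosome 14, 22920511 to 22929585) had a log2 fold change of 0.06 with PRT220 (edgeR adjusted p = 0.523).

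The libraries also split by a feature that the labels did not name. In 8 of them RRP9, a processing factor of ribosomal RNA precursors (ENSG00000114767, chromosome 3, 51933430 to 51941941), was measured at 0.677 to 1.73 CPM before scaling between libraries, against 29.1 to 36.1 CPM in the other 16. These 8 were DMSO C, PRT220 A, B and C, the PRT220 combination C, MS023 A and C, and the MS023 combination B. Between the 8 and the 16 libraries, 533 genes were lower and 163 were higher in edgeR's test with the groups accounted for. All 9 tested genes with symbols starting with RRP were lower, with a median log2 difference of -3.02, as were MT-CYB (-4.29), MT-ND5 (-4.07), MT-ND6 (-3.69) and MT-ND4 (-1.69), while the other 9 mitochondrial transcripts lay between -0.48 (MT-ND4L) and -0.12 (MT-CO1). All PRT220 libraries and 1 DMSO library belonged to the 8. Fits with a term for them, and fits of the 8 or the 16 alone, are therefore given with the results or further below.

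**Figure D1:**
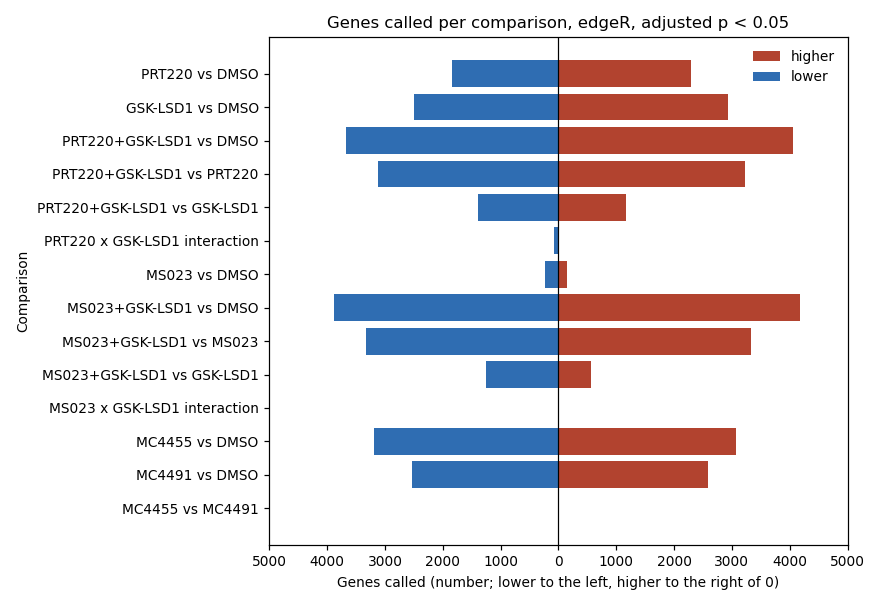
Number of genes called higher (right of 0) and lower (left of 0) in each of the 14 comparisons by edgeR's quasi-likelihood test at an adjusted p below 0.05, with 3 libraries per group. The combinations against DMSO gave 7735 and 8054 calls, and the MS023 interaction and MC4455 against MC4491 gave 0.

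The comparison of PRT220 with DMSO asked what PRMT5 inhibition alone did. By camera, monocyte and antigen presentation genes were higher with PRT220, with 9 of 21 and 6 of 17 members called up, and genes of cholesterol synthesis and of the amino acid stress response were lower. None of these 4 list calls held with an estimated correlation (adjusted p from 0.0972 to 0.126 in camera), and only that of the p53 targets did. KIT, the receptor for stem cell factor (ENSG00000157404, chromosome 4, 54657918 to 54740715), rose from 6.67 ± 0.856 to 29.2 ± 1.93 CPM (SD, n = 3), a log2 fold change of 2.13 ± 0.102 (SE, edgeR adjusted p = 2.95e-11). IGF1, a growth factor (ENSG00000017427, chromosome 12, 102395874 to 102481744), rose from 5.09 ± 0.741 to 21.6 ± 4.04 CPM. GATA2, a transcription factor of blood progenitors (ENSG00000179348, chromosome 3, 128479427 to 128493185), fell from 55.2 ± 2.54 to 22.2 ± 4.64 CPM. TRIB3, a stress-induced pseudokinase (ENSG00000101255, chromosome 20, 362835 to 397559), fell from 53.5 ± 14.2 to 18.0 ± 3.93 CPM.

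Among the largest rises were also GASK1B (log2 fold change 2.24), JAML, an adhesion molecule of leukocytes (1.85), GAPT (1.80), SLC4A3 (1.75), CYBB, the catalytic subunit of the phagocyte oxidase (1.51), CFP, the complement factor properdin (1.40), and CD84 (1.36). Among the largest falls were OCSTAMP, VWF (-1.37), GATA2 (-1.31), LINC03040 (-1.27) and NIBAN1 (-1.21). RRP7A and FTSJ1 had log2 fold changes of -3.76 and -2.18, which were -0.31 and -0.28 with the term for the 8 libraries. ITGAM, which encodes the myeloid integrin CD11b (ENSG00000169896, chromosome 16, 31259967 to 31332892), rose from 3.03 ± 0.804 to 7.06 ± 0.441 CPM. CD86 (log2 fold change 0.10, edgeR adjusted p = 0.778), MYC (0.06, 0.591), GFI1 (-0.03) and CDKN1A (0.09, 0.415) did not pass the test.

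In the cholesterol synthesis list 18 of 20 members fell and 0 rose, and the number of calls adjusted over the list alone was also 18. HMGCS1, which makes the precursor of mevalonate (ENSG00000112972, chromosome 5, 43289395 to 43313512), fell from 674 ± 53.2 to 412 ± 52.7 CPM, with falls in FDPS (-0.62) and INSIG1 (-0.56). The list was lower by camera (adjusted p = 3.34e-14; adjusted p = 0.126 with an estimated correlation). Of 25 ATF4 and amino acid response genes, 17 fell, or 19 adjusted over the list alone, among them PCK2 (-1.14), DDIT3 (-1.05) and SLC7A11 (-0.87), with camera adjusted p = 4.78e-10 and adjusted p = 0.0972 with an estimated correlation. Endoplasmic reticulum chaperones fell in 8 of 14 cases, 11 adjusted over the list alone, as in HSPA5 (-0.34; camera adjusted p = 0.00191, adjusted p = 0.564 with an estimated correlation). Of 27 p53 target genes, 15 rose and 1 fell, or 18 calls adjusted over the list alone. EDA2R, a receptor of the TNF family, rose from 4.18 ± 0.369 to 10.2 ± 1.64 CPM, and PLK2 (0.67) and BAX (0.49) rose as well, while CDKN1A was not called. The p53 list was the one whose camera call (adjusted p = 1.81e-10) held with an estimated correlation (adjusted p = 0.017).

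Of 21 monocyte and macrophage markers, 9 rose and 1 fell, or 11 calls adjusted over the list alone (camera adjusted p = 0.000651, adjusted p = 0.0972 with an estimated correlation). The list's median log2 fold change was 0.27, and 0.21 with the term for the 8 libraries. Antigen presentation genes rose in 6 of 17 cases, 6 adjusted over the list alone, as in HLA-DRA (0.71) and its activator CIITA (0.64), with camera adjusted p = 0.00227 and adjusted p = 0.126 with an estimated correlation. S phase genes fell in 10 of 26 cases, 10 adjusted over the list alone, with POLA1, the catalytic subunit of DNA polymerase alpha, at -0.80 and RRM2 at -0.60 (camera adjusted p = 0.000131, adjusted p = 0.564 with an estimated correlation). The S phase count includes UHRF1, whose -1.05 became -0.07 with the term for the 8 libraries. G2 and M phase genes fell in 9 of 26 cases, 9 adjusted over the list alone, as in TOP2A (-0.53; camera adjusted p = 0.00227, adjusted p = 0.667 with an estimated correlation). MAPK and STAT5 feedback genes fell in 8 of 20 cases and rose in 1, DUSP4 (0.68), or 9 calls adjusted over the list alone; ETV4 fell (-0.73; camera adjusted p = 0.0231, adjusted p = 0.633 with an estimated correlation).

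The other 16 lists were not called with PRT220. Members called up and down numbered 1 and 1 of 14 granulocyte genes, 1 and 2 of 15 LSD1-CoREST-GFI1 members, 1 and 1 of 15 MLL-fusion targets, 4 and 3 of 12 stem and progenitor markers, 1 and 4 of 26 MYC and ribosome biogenesis genes, and 7 and 2 of 33 interferon-stimulated genes. For NF-kB genes the numbers were 1 and 3 of 14, for the BCL2 family 3 and 3 of 15, for arginine methyltransferases 1 and 3 of 14, for splicing factors 7 and 0 of 27, and for DNA repair genes 5 and 8 of 19. Of the latter, RAD52 rose (0.81) and FANCD2 fell (-0.48). Markers of other lineages were called up and down in 0 and 2 of 7 erythroid, 2 and 0 of 11 neuronal, 0 and 1 of 9 lymphocyte and 2 and 0 of 6 epithelial genes. Of 13 mitochondrial transcripts MT-CYB and MT-ND6 were lower. With the term for the 8 libraries neither was called, and RRP9, among the 4 lower MYC list genes, rose. The 16 lists had camera adjusted p from 0.152 (stem and progenitor markers) to 0.958 (interferon-stimulated genes).

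Over all genes PRT220 gave 4139 calls, 2300 higher and 1839 lower, of which 158 and 147 changed at least 2-fold. In 3896 of the calls the libraries of the groups did not overlap, as in 36.7% of the genes tested, where chance gives 10% for 3 against 3. With the term for the 8 libraries 3940 genes were called, 3332 of them also without it. A fit within those 8 left 1 DMSO library, which is assumed to vary like the other groups. There, 99.7% of the genes called in the full fit and tested again kept their sign. Both fits share libraries, so most signs had to be the same.

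GSK-LSD1 alone addressed the effect of LSD1 inhibition. It raised monocyte and antigen presentation genes, some by large factors. Cholesterol synthesis genes and 9 of 14 granulocyte genes fell, in list calls that did not hold with an estimated correlation (camera adjusted p = 0.0569 for either). FCRLA, an intracellular Fc receptor-like protein (ENSG00000132185, chromosome 1, 161706972 to 161714352), rose from 0.362 ± 0.225 to 69.7 ± 6.02 CPM. VCAN, a matrix proteoglycan made by monocytes (ENSG00000038427, chromosome 5, 83471465 to 83582303), rose from 9.65 ± 0.634 to 598 ± 17.9 CPM, a log2 fold change of 5.95 ± 0.288 (SE, edgeR adjusted p = 1.94e-12). ITGAM rose to 26.4 ± 3.02 CPM, and CD86, a costimulatory ligand (ENSG00000114013, chromosome 3, 122055366 to 122121139), rose from 3.49 ± 1.47 to 26.2 ± 2.00 CPM. IGF1 rose to 129 ± 3.03 CPM and GATA2 fell by 1.2 on the log2 scale.

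Large rises were also found in RTN4RL1 (log2 fold change 4.99), RBM47 (4.45), KCTD12 (4.22), TICAM2, an adaptor of Toll-like receptor signalling (4.11), WFS1 (3.96) and SYT2 (3.91). The largest falls included IGLL1, a part of the pre-B-cell receptor (-2.98), CX3CR1, a chemokine receptor (-2.35), SLC13A3 (-2.11), NIBAN1 (-2.07), PTGER2 (-2.02), PEG3 (-2.00) and UNC5B (-1.95). CES1, a carboxylesterase of monocytes, fell from 40.3 ± 3.45 to 7.14 ± 0.753 CPM. MYC fell from 312 ± 10.4 to 210 ± 7.61 CPM, CDKN1A fell by 0.55 on the log2 scale, and GFI1, the repressor that LSD1 serves (ENSG00000162676, chromosome 1, 92474762 to 92486876), rose from 318 ± 7.70 to 409 ± 8.61 CPM. PRMT5 fell by 0.22 on the log2 scale, and PRMT1 was not called (-0.06, edgeR adjusted p = 0.461).

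Of 21 monocyte and macrophage markers, 11 rose and 3 fell, 15 adjusted over the list alone, and the list's call held with an estimated correlation (camera adjusted p = 1.08e-09, adjusted p = 0.00261 with an estimated correlation). Of 17 antigen presentation genes, 10 rose and 0 fell, 11 adjusted over the list alone, with a median log2 fold change of 1.44, and this call held as well (camera adjusted p = 7.88e-10, adjusted p = 0.00287 with an estimated correlation). Granulocyte and granule genes went both ways. Of 14, 9 fell and 3 rose, 13 adjusted over the list alone, as in CTSG, the protease cathepsin G (-1.68), against MMP9 (2.24). Their median was -0.97 and their mean 0.06, so that the mean differed in sign from the median and from the test, which was lower (camera adjusted p = 0.000406, adjusted p = 0.0569 with an estimated correlation).

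Cholesterol synthesis genes fell in 18 of 20 cases, 18 adjusted over the list alone, with a median of -0.70, as in MVD (-0.98), HMGCS1 (-0.88) and LSS (-0.84); the camera adjusted p was 4.66e-20, with adjusted p = 0.0569 with an estimated correlation. Of 26 S phase genes 18 fell and 1 rose, 20 adjusted over the list alone, with MCM2 at -0.40 (camera adjusted p = 8.2e-05, adjusted p = 0.607 with an estimated correlation). Of 26 G2 and M phase genes 8 fell, 8 adjusted over the list alone, and of 26 MYC and ribosome biogenesis genes 8 fell, 9 adjusted over the list alone; each had camera adjusted p = 0.0125 and adjusted p = 0.777 with an estimated correlation. ATF4 and amino acid response genes fell in 12 of 25 cases and rose in 1, 15 adjusted over the list alone, as in TRIB3 (-1.84) and SLC7A11 (-0.82; camera adjusted p = 0.00306, adjusted p = 0.607 with an estimated correlation). The p53 targets were called up in 7 and down in 6 of 27 cases, with rises in TIGAR (1.30) and TP53I3 (1.00), and the list was not called (camera adjusted p = 0.975).

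Within lists that were not called, DUSP4, a phosphatase that dampens MAPK signalling, rose from 3.74 ± 0.566 to 24.5 ± 1.21 CPM while EGR1 fell (-0.71), ICAM1 rose (0.99), OAS1 rose (1.2), GFI1B rose (1.78), BCL2 fell (-0.41) and KLF1, an erythroid regulator at low level, fell (-1.69). Of markers of other cell types, the epithelial KRT8 rose (0.81), as did, at low level, DCN (2.88) and the lymphocyte GNLY (3.72). Of the neuronal list L1CAM (1.41), CHGB (1.85) and RUNDC3A (0.30) rose, but lost the call in 4 of 14, 5 of 12 and 10 of 14 alternatives, RUNDC3A also with the term for the 8 libraries. The erythroid NFE2 fell (-0.94). GSK-LSD1 gave 5419 calls in total, 2925 higher and 2494 lower, with 560 and 226 changed at least 2-fold, and the groups did not overlap in 5220 of them (and in 46.3% of all genes tested, against 10% by chance). The 16 libraries without the RRP9 loss, among which were all of GSK-LSD1, gave 4873 calls. There, every gene called in the full fit and tested again kept its sign, in fits that share these libraries.

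**Figure D2:**
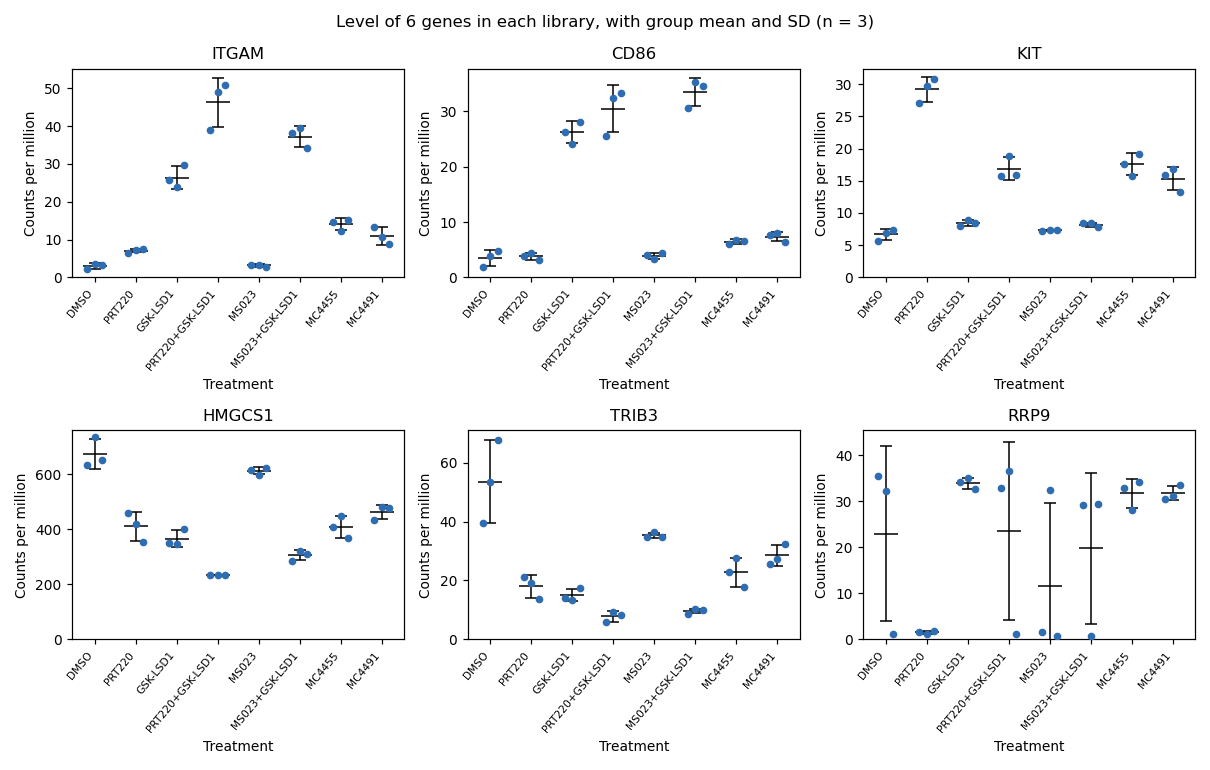
Level in CPM of ITGAM, CD86, KIT, HMGCS1, TRIB3 and RRP9 in each of the 24 libraries by group, where points are libraries and the bar with whiskers is the group mean and SD (n = 3). ITGAM was highest with PRT220 and GSK-LSD1 together, at 46.3 ± 6.42 CPM, and RRP9 lay between 0.677 and 1.73 CPM in 8 libraries.

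The combination of PRT220 and GSK-LSD1 was the treatment whose effect on growth the series set out to understand. Against DMSO it gave rises in monocyte and antigen presentation genes and falls in cholesterol synthesis genes. Amino acid response and cell cycle genes fell as well, but those list calls did not hold with an estimated correlation (camera adjusted p of 0.176 for the former, 0.127 for S phase and 0.372 for G2 and M phase). FCRLA rose to 99.1 ± 7.43 CPM, VCAN to 494 ± 22.9 CPM, IGF1 to 217 ± 19.8 CPM and ITGAM to 46.3 ± 6.42 CPM, the last with a log2 fold change of 3.91 ± 0.173 (SE, edgeR adjusted p = 2.99e-13). ZNF366, a transcriptional regulator of dendritic cells, rose from 0.311 ± 0.0780 to 15.3 ± 0.912 CPM. CYBB rose from 3.60 ± 0.216 to 42.7 ± 2.73 CPM and CD86 rose to 30.4 ± 4.23 CPM. TRIB3 fell to 7.80 ± 1.80 CPM and HMGCS1 to 233 ± 0.580 CPM.

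Further large rises were RTN4RL1 (log2 fold change 5.29), RBM47 (4.26) and WFS1 (4.03). Further large falls were SEPTIN5 (-3.49), IGLL1 (-2.94), SLC13A3 (-2.74), NIBAN1 (-2.58), OCSTAMP (-2.30) and CES1 (-2.23), and PRTN3, which encodes the granule protease proteinase 3, fell from 104 ± 3.10 to 19.0 ± 1.17 CPM. MYC fell to 213 ± 25.6 CPM, CDKN1A fell by 0.45 and GFI1 rose by 0.28 on the log2 scale. Among stem and progenitor markers, which went both ways, GATA2 fell (-2.15), CD38 rose (1.97) and KIT rose to 16.8 ± 1.79 CPM. Among markers of other cell types KRT8 (1.27), SYN1 (1.97), L1CAM (1.58) and, at low level, GNLY (4.23) and DCN (3.40) rose. NFE2 (-1.17), KLF1 (-2.28) and TRAC (-1.16) fell, and none of their lists was called.

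All 20 cholesterol synthesis genes fell, 20 adjusted over the list alone, with a median of -1.03, as in MVD (-1.34) and CYP51A1 (-1.26). The call held with an estimated correlation (camera adjusted p = 3.84e-30, adjusted p = 0.0149 with an estimated correlation). So did those of monocyte and macrophage markers, of which 14 of 21 rose and 3 fell, 17 adjusted over the list alone (camera adjusted p = 1.06e-09, adjusted p = 0.00298 with an estimated correlation), and of antigen presentation genes, of which 11 of 17 rose and 0 fell, 11 adjusted over the list alone (camera adjusted p = 2.84e-08, adjusted p = 0.00904 with an estimated correlation). Of 26 S phase genes 22 fell, 23 adjusted over the list alone, with a median of -0.43, as in POLA1 (-0.90), RRM2 (-0.88) and MCM4 (-0.61; camera adjusted p = 9.68e-13, adjusted p = 0.127 with an estimated correlation). Of 26 G2 and M phase genes 23 fell, 25 adjusted over the list alone, as in TOP2A (-0.60) and CCNA2 (-0.57; camera adjusted p = 6.28e-08, adjusted p = 0.372 with an estimated correlation). Of 26 MYC and ribosome biogenesis genes 15 fell, 15 adjusted over the list alone (camera adjusted p = 0.00448, adjusted p = 0.542 with an estimated correlation).

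ATF4 and amino acid response genes fell in 19 of 25 cases and rose in 1, 20 adjusted over the list alone, as in SLC7A11 (-1.36), DDIT3 (-1.2) and CHAC1 (-1.2; camera adjusted p = 1.5e-06, adjusted p = 0.176 with an estimated correlation). Endoplasmic reticulum chaperones fell in 11 of 14 cases and rose in 1, 13 adjusted over the list alone, as in CALR (-0.49) and HSPA5 (-0.46; camera adjusted p = 0.000749, adjusted p = 0.393 with an estimated correlation). In the granulocyte list 9 of 14 fell and 3 rose, 13 adjusted over the list alone, with a median of -0.99, a mean of 0.08 and a test that was lower (camera adjusted p = 0.00234, adjusted p = 0.127 with an estimated correlation). The p53 targets were higher and the DNA repair genes lower, each with camera adjusted p = 0.0495, with adjusted p = 0.407 and adjusted p = 0.542 with an estimated correlation. Of the former 11 of 27 rose and 4 fell, 15 adjusted over the list alone, as in TIGAR (1.38) and ZMAT3 (1.16), and of the latter 12 of 19 fell and 5 rose, 17 adjusted over the list alone, as in FANCD2 (-0.69) and ATM (0.67). Both calls ended with the term for the 8 libraries (adjusted p = 0.0595 each), and the p53 call also with DESeq2's size factors (adjusted p = 0.0554).

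The combination gave 7735 calls, 4064 higher and 3671 lower, with 828 and 337 changed at least 2-fold, and the groups did not overlap in 7331 of them (and in 53% of all genes tested, against 10% by chance). With the term for the 8 libraries there were 8144 calls, and within the other 16 libraries 6719.

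**Figure D3:**
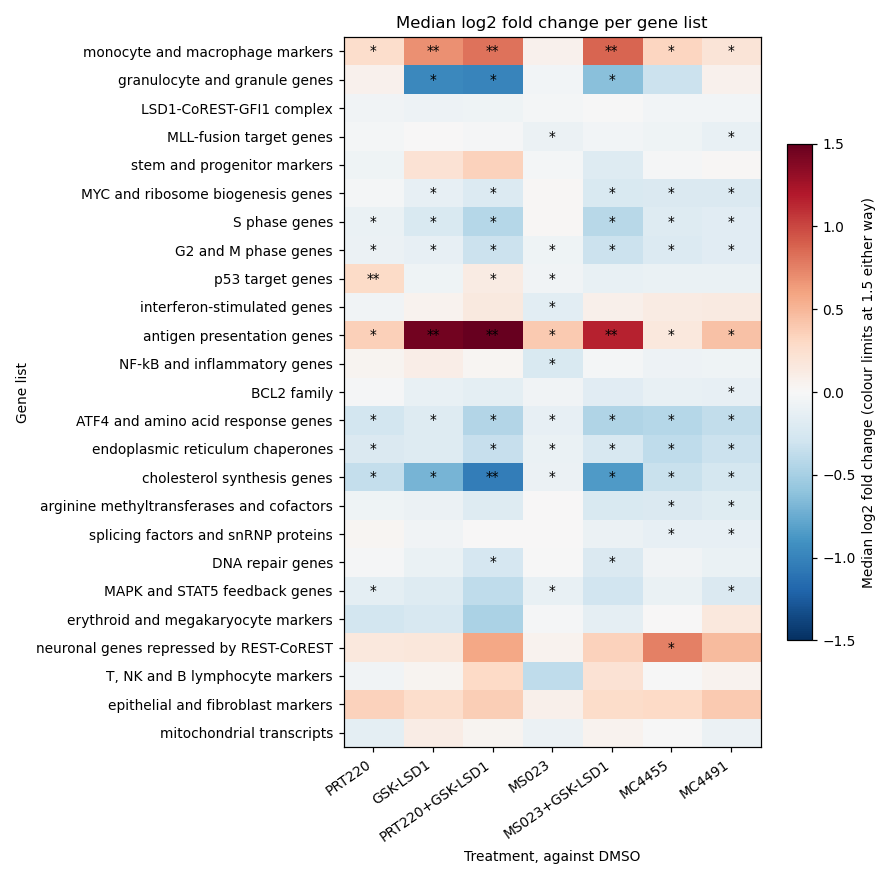
Median log2 fold change against DMSO of the tested members of each of the 25 gene lists in the 7 treatments, with colours limited at 1.5 on either side; * marks camera adjusted p below 0.05 and ** a call that also held with an estimated correlation. Cholesterol synthesis genes were lower in every column, with medians down to -1.03.

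Adding GSK-LSD1 to PRT220 asked what LSD1 inhibition contributed on top of PRMT5 inhibition. FCRLA was higher in the combination than with PRT220 alone (99.1 ± 7.43 against 0.324 CPM), as were VCAN (log2 fold change 5.95), RTN4RL1 (4.48), KCTD12 (4.14), RBM47 (4.14), CD86 (3.00) and ITGAM (2.71). IGLL1 (-3.78), CES1 (-2.84), IL7R, the interleukin-7 receptor (-2.50), and PRTN3 (-2.47) were lower. KIT, raised by PRT220, fell from 29.2 ± 1.93 to 16.8 ± 1.79 CPM, and MYC fell from 324 ± 14.5 to 213 ± 25.6 CPM (edgeR adjusted p = 3.3e-07). Cholesterol synthesis genes fell in 18 of 20 cases, 18 adjusted over the list alone (camera adjusted p = 1.39e-16, adjusted p = 0.0916 with an estimated correlation). Monocyte markers rose in 13 of 21 cases and fell in 4, 18 adjusted over the list alone (camera adjusted p = 5.78e-07, adjusted p = 0.0179 with an estimated correlation), and antigen presentation genes rose in 9 of 17 and fell in 1, 11 adjusted over the list alone (camera adjusted p = 3.87e-06, adjusted p = 0.0325 with an estimated correlation). Granulocyte genes fell in 10 of 14 cases and rose in 3, 13 adjusted over the list alone (camera adjusted p = 0.000103, adjusted p = 0.0383 with an estimated correlation), with a mean of 0.01 against a median of -1.02. Of the 26 S phase genes 20 fell and 1 rose, 22 adjusted over the list alone (camera adjusted p = 1.75e-08, adjusted p = 0.319 with an estimated correlation). Of the 26 G2 and M phase genes 17 fell, 18 adjusted over the list alone (camera adjusted p = 3.63e-05, adjusted p = 0.698 with an estimated correlation), and of the 26 MYC and ribosome biogenesis genes 13 fell and 2 rose, 17 adjusted over the list alone (0.0105, adjusted p = 0.713 with an estimated correlation). The 2 that rose were RRP9 and RRP12, with log2 fold changes of 3.93 and 2.63 that were -0.38 and -0.01 with the term for the 8 libraries, and the list's mean, 0.10, differed in sign from its median, -0.15, and its test. Markers of other cell types moved too: the neuronal L1CAM (2.66) and RUNDC3A (0.42), the lymphocyte GNLY (3.63, to 0.320 CPM) and CD8A (1.26), the epithelial KRT8 (0.75) and the megakaryocyte ITGA2B (0.31) were higher. The erythroid NFE2 (-0.90) was lower. RUNDC3A, GNLY and CD8A were not called within the 8 libraries. The neuronal SCG2 (1.65) lost its call in 7 of 13 alternatives and SYN1 (1.40) in 6 of 13, among them the term for the 8 libraries. MT-CYB (3.31), MT-ND5 (3.14) and MT-ND6 (2.92) were called higher, but were lower and not called with the term for the 8 libraries. In total 6350 genes were called, 3227 higher and 3123 lower. With the term there were 5050, 4734 of them also called without it.

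Adding PRT220 to GSK-LSD1 asked the converse and gave smaller changes. ZNF366 rose from 4.73 ± 0.835 to 15.3 ± 0.912 CPM, CYBB from 18.1 ± 0.831 to 42.7 ± 2.73 CPM and ITGAM from 26.4 ± 3.02 to 46.3 ± 6.42 CPM (edgeR adjusted p = 0.000788). GAPT, JAML (1.09), CD38 (1.04) and KIT (1.00) rose as well. GATA2 (-0.95), CRYL1 (-0.98) and PRTN3 (-0.91) fell, and CD86 (0.22, edgeR adjusted p = 0.501) and MYC (0.02) were not called. Cholesterol synthesis genes fell in 16 of 20 cases, 17 adjusted over the list alone, with HMGCS1 going from 366 ± 30.5 to 233 ± 0.580 CPM (camera adjusted p = 1.74e-17, adjusted p = 0.101 with an estimated correlation). S phase genes fell in 17 of 26 cases, 21 adjusted over the list alone, as in POLA1 and RRM2 (-0.58; camera adjusted p = 6.21e-17, adjusted p = 0.101 with an estimated correlation), and G2 and M phase genes in 16 of 26, 20 adjusted over the list alone, as in TOP2A (-0.57; camera adjusted p = 2.1e-12, adjusted p = 0.177 with an estimated correlation). Of 27 p53 targets 9 rose, 12 adjusted over the list alone, with EDA2R at 0.94 (camera adjusted p = 2.7e-06, adjusted p = 0.101 with an estimated correlation), and of 25 ATF4 genes 12 fell, 12 adjusted over the list alone, with PCK2 at -0.80 (camera adjusted p = 9.42e-07, adjusted p = 0.177 with an estimated correlation). The remaining camera calls were chaperones (lower, 9.12e-05, adjusted p = 0.267 with an estimated correlation), monocyte markers (higher, 0.00948, adjusted p = 0.177 with an estimated correlation) and MAPK and STAT5 feedback genes (lower, 0.0188, adjusted p = 0.531 with an estimated correlation). In total 2553 genes were called, 1166 higher and 1387 lower. Without replicate B of the combination there were 1662, and within the 16 libraries 2018.

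The interaction asked which genes in the combination departed from the sum of the single-agent changes on the log2 scale. It called 90 genes, 17 above and 73 below the sum. Below it were KIT (interaction -1.13 ± 0.141, SE, edgeR adjusted p = 0.000672), IGF1 (-1.31 ± 0.206, adjusted p = 0.00309), MPEG1, a pore-forming protein of macrophages (-0.97), CD84 (-0.91), the lipid transporter gene ABCA6 (-0.91), ENPP2 (-0.71) and LYZ, which encodes lysozyme (-0.55). MPEG1 was at 44.2 ± 2.92 CPM with DMSO, 94.7 ± 7.21 with PRT220, 154 ± 5.54 with GSK-LSD1 and 168 ± 9.91 with both. Above the sum were KDM7A, a histone demethylase (1.2 ± 0.163, adjusted p = 0.00103), and RHOQ (0.50). KDM7A fell from 2.81 ± 0.263 to 1.18 ± 0.0308 CPM with PRT220 alone but was at 19.8 ± 0.981 with GSK-LSD1 and 19.0 ± 2.05 CPM with both. These 9 genes were called under all 19 alternatives that did not also ask for a log2 fold change of at least 1. ITGAM (-0.39, edgeR adjusted p = 0.605), CD86 (0.11, 0.939), MYC (-0.04) and CDKN1A (0.01) were not called.

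Of the 73 genes below the sum, 72 were raised by PRT220, 52 by GSK-LSD1 and 58 by the combination, with median log2 fold changes of 0.58, 0.38 and 0.63. The camera test called 6 lists and none held with an estimated correlation. Monocyte markers were lower (1 of 21 members called, 5 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.272 with an estimated correlation). With 0 members called over all genes, p53 targets (3 adjusted over the list alone, camera adjusted p = 0.000327, adjusted p = 0.18 with an estimated correlation) and antigen presentation genes (5 adjusted over the list alone, 0.000658, adjusted p = 0.18 with an estimated correlation) were lower and ATF4 genes were higher (0.000658, adjusted p = 0.626 with an estimated correlation). S phase genes (0.000658, adjusted p = 0.917 with an estimated correlation) and G2 and M phase genes (0.00176, adjusted p = 0.956 with an estimated correlation) were called too, with 0 members called. The number of interaction calls rested on single libraries. It was 27 without PRT220 C, between 39 and 53 without DMSO B, PRT220 B, or any 1 library of GSK-LSD1 or of the combination, 54 with no filter, and 198 in DESeq2, and it was 85, 16 above and 69 below, with the term for the 8 libraries.

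**Figure D4:**
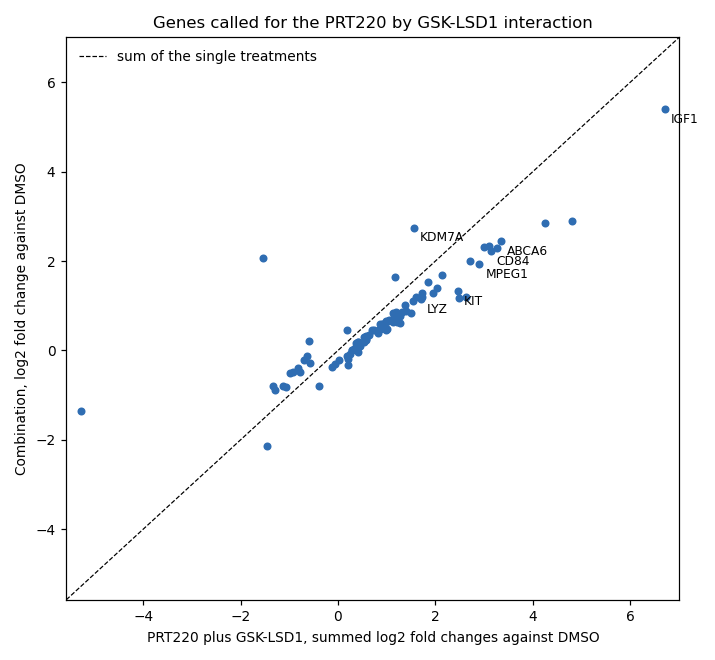
For the 90 interaction genes, the sum of the log2 fold changes of PRT220 and GSK-LSD1 alone (horizontal) against the log2 fold change of the combination (vertical), each against DMSO, with the dashed line where both are equal. Of these genes 73 lie below the line and 17 above it.

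MS023 alone, which inhibits the enzymes for asymmetric arginine methylation, changed fewer genes and by less. GNG7, a G protein subunit (ENSG00000176533, chromosome 19, 2511219 to 2702709), rose from 18.0 ± 1.70 to 29.6 ± 0.331 CPM (log2 fold change 0.71 ± 0.081, SE, edgeR adjusted p = 0.000196), with rises in SDK2 (0.71), PRR22 (0.63) and VAT1L (0.62). CCND1, which encodes cyclin D1, fell from 5.75 to 3.26 CPM (-0.82), with falls in PDGFA (-0.72) and PHLDA1 (-0.68). HLA-DRA rose from 11.3 ± 0.465 to 17.4 ± 0.999 CPM and CD74, the invariant chain, from 113 ± 2.21 to 158 ± 10.8 CPM, and MYC rose from 312 ± 10.4 to 376 ± 10.1 CPM. CDKN1A fell by 0.32 on the log2 scale, while ITGAM (0.06, edgeR adjusted p = 0.912), CD86 (0.15, 0.797), KDM1A (0.01) and PRMT1 (-0.05, 0.75) were not called. Of 17 antigen presentation genes 3 rose, 4 adjusted over the list alone (camera adjusted p = 0.000154, adjusted p = 0.142 with an estimated correlation). NF-kB genes fell in 2 of 14 cases, 6 adjusted over the list alone, as in NFKB1 (-0.25; 0.000154, adjusted p = 0.412 with an estimated correlation), and MAPK and STAT5 feedback genes in 2 of 20, 6 adjusted over the list alone (0.00276, adjusted p = 0.593 with an estimated correlation). Another 7 lists were called by camera with at most 2 members called, and for them adjusted p with an estimated correlation ran from 0.412 to 0.626. In total 375 genes were called, 148 higher and 227 lower. The calls named here for MS023 rest on the spread pooled over all 24 libraries, since a fit of DMSO and MS023 alone called 0 genes in edgeR. Fits of all groups gave 2510 genes at an unadjusted p below 0.05 in edgeR and 626 calls in DESeq2. With 1 library left out of the fit of all groups, edgeR called 185 without MS023 A, 193 without MS023 B and 194 without DMSO B.

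MS023 with GSK-LSD1 against DMSO again raised monocyte and antigen presentation genes. FCRLA rose to 98.1 ± 7.55 CPM, VCAN to 626 ± 16.4 CPM, IGF1 to 133 ± 7.52 CPM, ITGAM to 37.2 ± 2.77 CPM and CD86 to 33.4 ± 2.52 CPM (log2 fold change 3.25, edgeR adjusted p = 7.4e-11). CES1 fell to 6.25 CPM, TRIB3 to 9.60 CPM and HMGCS1 to 306 ± 17.4 CPM, and IGLL1 and NIBAN1 fell by 3.91 and 2.38 on the log2 scale. CDKN1A fell from 102 to 56.9 CPM and MYC by 0.31 on the log2 scale. Of 21 monocyte markers 15 rose and 3 fell, 18 adjusted over the list alone (camera adjusted p = 3.01e-08, adjusted p = 0.00365 with an estimated correlation), and of 17 antigen presentation genes 12 rose and 1 fell, 14 adjusted over the list alone (1.87e-11, adjusted p = 0.00365 with an estimated correlation). All 20 cholesterol synthesis genes fell, as in MVD (-1.10) and IDI1 (-1.01; 20 adjusted over the list alone, 1.94e-21, adjusted p = 0.0522 with an estimated correlation). S phase genes fell in 23 of 26 cases, 24 adjusted over the list alone (1.05e-09, adjusted p = 0.223 with an estimated correlation), G2 and M phase genes in 21 of 26, 23 adjusted over the list alone, as in CCNA2 (-0.66; 4.52e-08, adjusted p = 0.322 with an estimated correlation), and ATF4 genes in 20 of 25 with 4 rises, 24 adjusted over the list alone, as in SLC7A11 (-1.44; 7.11e-06, adjusted p = 0.223 with an estimated correlation). For the 4 other lists called by camera, adjusted p with an estimated correlation ran from 0.132 to 0.585. One of them, the granulocyte list, was lower by the test and the median (-0.63) but not by the mean (0.06). Among markers of other cell types KRT8 (1.23), ITGA2B (0.40), SYN1 (1.67) and, at low level, GNLY (4.31) and DCN (2.74) rose, as did L1CAM (1.16), whose call was lost in 7 of 15 alternatives. NFE2 (-0.68), KLF1 (-1.58) and TRAC (-1.45) fell, and none of their lists was called. In total 8054 genes were called, 4176 higher and 3878 lower, with 7391 within the 16 libraries.

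Against MS023 alone the combination differed in 6659 genes, 3326 higher and 3333 lower, led by FCRLA, VCAN (5.58), RTN4RL1 (5.06), IGF1 (4.62) and TICAM2 (4.59) above and IGLL1 (-3.78), SEPTIN5 (-2.85), CES1 (-2.66), IL7R (-2.28) and CX3CR1 (-1.97) below. Monocyte markers (14 of 21 up, 3 down, 18 adjusted over the list alone, camera adjusted p = 2.56e-09, adjusted p = 0.00413 with an estimated correlation) and antigen presentation genes (11 of 17 up, 2 down, 13 adjusted over the list alone, 1.4e-09, adjusted p = 0.00413 with an estimated correlation) held, and 9 other camera calls had adjusted p from 0.0648 to 0.624 with an estimated correlation. Granulocyte genes were again lower by the test and the median (-0.67) but not by the mean (0.25). Markers of other cell types moved as well, with SYN1 (2.85), L1CAM (1.46), KRT8 (0.96) and, at low level, GNLY (6.79) higher and NFE2 (-0.66) lower. L1CAM and NFE2 were not called within the 16 libraries, nor SYN1 within the 8. The 16 libraries, with 1 of MS023, gave 3359 calls and the 8, with 1 of the combination, gave 3536. Against GSK-LSD1 alone the combination differed in 1808 genes, 560 higher and 1248 lower. CD74 rose from 306 ± 5.31 to 476 ± 23.5 CPM and HLA-DRA by 0.58 on the log2 scale, and NOS2, an inducible nitric oxide synthase, fell from 13.1 ± 1.51 to 7.13 ± 0.627 CPM (edgeR adjusted p = 0.0013), with a fall in ABCA1, a cholesterol exporter (-0.73). G2 and M phase genes fell in 16 of 26 cases, 20 adjusted over the list alone (camera adjusted p = 2.13e-13, adjusted p = 0.327 with an estimated correlation). S phase genes fell in 11 of 26, 19 adjusted over the list alone (camera adjusted p = 2.41e-09, adjusted p = 0.327 with an estimated correlation), and antigen presentation genes rose in 6 of 17 and fell in 1, 9 adjusted over the list alone (0.00015, adjusted p = 0.186 with an estimated correlation). The 4 other camera calls had adjusted p from 0.327 to 0.614 with an estimated correlation. The 1808 calls fell to 465 without GSK-LSD1 B and rose to 2945 with the term for the 8 libraries.

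The interaction of MS023 with GSK-LSD1 called 0 genes in edgeR, with 1356 at an unadjusted p below 0.05, 19 in DESeq2, 2 within the 16 libraries, and 1 each without GSK-LSD1 A and without MS023 C. Camera called 7 lists with 0 members called, S phase genes with adjusted p = 2.59e-14, and for these 7 adjusted p with an estimated correlation ran from 0.442 to 0.726.

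MC4455 and MC4491 are compounds given by code names, and each was compared with DMSO and with the other. By camera, monocyte and antigen presentation genes were higher with MC4455 and chaperone, amino acid response and cell cycle genes lower, but 0 of the 11 list calls held with an estimated correlation. IGF1 rose from 5.09 ± 0.741 to 30.6 ± 6.88 CPM, SYT2 from 3.18 to 17.3 CPM, ITGAM to 14.1 ± 1.5 CPM (log2 fold change 2.19, edgeR adjusted p = 3.41e-08), KIT to 17.5 ± 1.70 CPM and HLA-DRA from 11.3 ± 0.465 to 28.8 ± 3.89 CPM. KLF2, a transcription factor (ENSG00000127528, chromosome 19, 16324817 to 16327874), RHOB and the phosphatase gene DUSP1 fell (-1.67, -1.26 and -1.25), as did TRIB3, to 22.7 ± 5.00 CPM, and HMGCS1, to 409 ± 39.2 CPM. CD38 (1.48) and CIITA (1.19) rose, PRMT1 (-0.34) and PRMT5 (-0.23) fell, and MYC was not called (-0.04, edgeR adjusted p = 0.642). Of 26 G2 and M phase genes 21 fell, 22 adjusted over the list alone (camera adjusted p = 7e-08, adjusted p = 0.306 with an estimated correlation). Of 14 chaperones 11 fell, 12 adjusted over the list alone, as in HYOU1 (-0.64; camera adjusted p = 4.21e-09, adjusted p = 0.0984 with an estimated correlation). Of 25 ATF4 genes 18 fell and 1 rose, 19 adjusted over the list alone (camera adjusted p = 2.55e-10, adjusted p = 0.0867 with an estimated correlation), and of 20 cholesterol synthesis genes 16 fell, 17 adjusted over the list alone (1.68e-12, adjusted p = 0.12 with an estimated correlation). Monocyte markers rose in 11 of 21 cases and fell in 1, 12 adjusted over the list alone (0.000114, adjusted p = 0.0784 with an estimated correlation). The 6 other camera calls had adjusted p from 0.0784 to 0.394 with an estimated correlation. Among them were the arginine methyltransferases and cofactors, of which 7 of 14 fell, as in WDR77, the partner of PRMT5 (-0.48), and the neuronal genes repressed by REST-CoREST, of which 3 of 11 rose, RUNDC3A (0.81), SYP (0.75) and CHGB (1.75, to 0.237 CPM, a call lost in 6 of 12 alternatives; camera adjusted p = 0.0224, adjusted p = 0.0984 with an estimated correlation). Of 6 epithelial and fibroblast markers 2 rose, KRT8 (0.70) and DCN (2.64, to 0.194 CPM), and the list was not called (camera adjusted p = 0.191). The megakaryocyte ITGA2B (0.67) and the lymphocyte CD3G (0.67) rose as well, and TRAC fell (-0.82), a call lost in 2 of 14 alternatives, the 16 libraries among them. MC4455 gave 6264 calls, 3071 higher and 3193 lower, and 5545 within the 16 libraries.

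With MC4491 IGF1 rose to 19.1 ± 2.43 CPM, ITGAM to 11.0 ± 2.33 CPM, CYBB to 10.9 ± 0.930 CPM (edgeR adjusted p = 1.09e-09), KIT to 15.3 ± 1.81 CPM and HLA-DRA to 22.8 ± 2.12 CPM, while KLF2 (-1.59), RHOB (-1.29), DUSP1 (-1.2), TRIB3 (-0.91), PCK2 (-0.81) and HYOU1 (-0.60) fell and HMGCS1 fell to 463 ± 26.8 CPM. CD86 rose by 1.05 and PRMT1 fell by 0.34 on the log2 scale, and MYC was not called (0.08, edgeR adjusted p = 0.397). Of 26 G2 and M phase genes 20 fell, 20 adjusted over the list alone (camera adjusted p = 7.76e-08, adjusted p = 0.22 with an estimated correlation), and of 25 ATF4 genes 17 fell, 19 adjusted over the list alone (6.33e-11, adjusted p = 0.063 with an estimated correlation). Of 21 monocyte markers 11 rose, 11 adjusted over the list alone (camera adjusted p = 2.12e-05, adjusted p = 0.0613 with an estimated correlation), and of 17 antigen presentation genes 7 rose, 9 adjusted over the list alone (2.88e-05, adjusted p = 0.063 with an estimated correlation). The 9 other camera calls had adjusted p from 0.16 to 0.469 with an estimated correlation. RUNDC3A (0.49), SYP (0.49), CHGB (2.25), KRT8 (0.54), DCN (3.08), ITGA2B (0.58) and CD3G (0.73), markers of other cell types, rose here too and TRAC fell (-0.86), in lists that were not called. Of these calls that of SYP was lost in 4 of 14 alternatives, that of CHGB without MC4491 C and that of TRAC within the 16 libraries. MC4491 gave 5112 calls, 2582 higher and 2530 lower, 4451 within the 16 libraries and 2963 when DMSO and MC4491 were fitted alone.

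Between MC4455 and MC4491 edgeR called 0 genes, with a smallest adjusted p of 0.228, against 780 genes at an unadjusted p below 0.05, 18 in DESeq2, 4 when the 2 groups were fitted alone, and 29 without MC4455 B. For the 6862 genes called against DMSO in either, the log2 difference, MC4455 minus MC4491, lay between -0.27 and 0.44, outermost 5% left out. For the 498 that had also changed at least 2-fold in either, it lay between -1.54 and 1.88. These are ranges of estimates over genes and exclude no difference. ITGAM differed by 0.36 ± 0.156 (SE, edgeR adjusted p = 0.982), CD86 by -0.19 ± 0.197, MYC by -0.12 ± 0.065 and PRMT1 by -0.01 ± 0.055. By camera, cholesterol synthesis genes were lower with MC4455 (median -0.12, 0 of 20 called, camera adjusted p = 1.47e-10, adjusted p = 0.357 with an estimated correlation), granulocyte genes were called (3 of 14 adjusted over the list alone, 0.000151, adjusted p = 0.0904 with an estimated correlation) and so were chaperones (0.0309, adjusted p = 0.968 with an estimated correlation). The labels gave no dose or time for either compound.

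Fold changes of the treatments were also correlated across genes, which are not independent replicates, in 21 pairs that share the DMSO libraries. Unchanged groups simulated against the same controls gave r = 0.479 and a covariance of 0.0861. The combinations of GSK-LSD1 with PRT220 and with MS023 had r = 0.769 and a covariance of 0.526, and 2940 genes were higher in both against 1020 for independent lists and 2804 lower in both against 856. For MC4455 and MC4491, r was 0.669 and the covariance 0.279, with 2259 genes higher in both against 477, 2255 lower in both against 485, and 0 in opposite directions. PRT220 and GSK-LSD1 had r = 0.315, below the simulated value, and a covariance of 0.148, with 896 genes higher in both against 404, 668 lower in both against 276, and 509 in opposite directions. Part of each excess may come from the shared controls, since 3 DMSO libraries cannot be split into groups of at least 2.

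Transcript usage, which PRMT5 inhibition is known to affect through splicing, changed in 1861 genes with PRT220, 591 with GSK-LSD1, 2243 with their combination, 502 with MS023, 1532 with MS023 and GSK-LSD1, 1682 with MC4455 and 1417 with MC4491 (limma's diffSplice, adjusted p below 0.05). The MS023 count does not stand out: another grouping of the MS023 and DMSO libraries gave 544, and it was 291 with the replicate letter as a block. With PRT220 the share of CDK5RAP3-201, a coding transcript, fell from 27.0% ± 0.850 to 6.98% ± 1.77 of its gene (SD, n = 3, limma diffSplice adjusted p = 2.49e-30). The retained-intron transcript MAN2B1-206 rose from 3.58% ± 0.444 to 9.33% ± 1.55 and FNTA-205, annotated as a target of nonsense-mediated decay, from 11.5% ± 0.707 to 30.0% ± 3.44. MDM4, a p53 inhibitor whose splicing is known to depend on PRMT5, shifted from MDM4-203 (72.8% ± 3.76 to 53.3% ± 5.65) to MDM4-205 (11.6% ± 1.5 to 31% ± 3.77; limma diffSplice adjusted p = 7.96e-05), while its gene level was not called (0.07). In the PRT220 combination MDM4-205 was at 29.2% ± 2.36 (0.000366), and MDM4 usage was not called with GSK-LSD1 (0.74), MS023 (0.978), MC4455 (0.258) or MC4491 (0.763). With GSK-LSD1 the share of XBP1-207 fell from 9.67% ± 0.940 to 2.13% ± 0.285 (4.48e-19). It was at 1.90% ± 0.351 in the PRT220 combination, 1.96% ± 0.258 in the MS023 combination, 1.29% ± 0.461 with MC4455 and 1.98% ± 0.322 with MC4491. Within the 8 libraries, which held 1 of DMSO, the PRT220 count was 840, and diffSpliceDGE called between 351 and 630 genes per treatment.

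The share of reads on retained-intron transcripts was 5.16% ± 0.0608 with DMSO (SD, n = 3). It was 5.5% ± 0.309 with PRT220, 5.40% ± 0.128 with GSK-LSD1, 5.92% ± 0.478 with both, 5.78% ± 0.524 with MS023 and GSK-LSD1, 6.15% ± 0.257 with MC4455 and 5.92% ± 0.148 with MC4491. In each of these 6 treatments every library lay above every DMSO library, which gives the smallest two-sided exact permutation p that 3 against 3 allows, 0.1 (Benjamini-Hochberg adjusted 0.117). The share with MS023 was 5.30% ± 0.436 (exact permutation p = 0.9, adjusted 0.9). With the term for the 8 libraries the difference of PRT220 from DMSO went from 0.337 to 0.710 percentage points and that of GSK-LSD1 from 0.242 to 0.0548. Single libraries moved these differences: that of PRT220 was 0.175 without PRT220 C, that of its combination went from 0.759 to 0.491 without replicate A, and that of the MS023 combination from 0.614 to 0.366 without replicate C.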

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

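Of the tests in this part, those with a term for the 8 libraries low in RRP9, and those on the RRP-named and ribosome biogenesis genes were chosen after the result was seen; the tests by regrouping the libraries, by simulated additive effects and by shared sequence were written before theirs.

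The interaction of PRT220 with GSK-LSD1, a test of whether the effect of 1 inhibitor differed with and without the other, called 90 genes. Above the sum of the single-agent log2 changes were KDM7A (1.2), PHLDA1 (0.81), NAB2 (0.53), RHOQ (0.50), CDC42EP3 (0.49), RAPGEF2 (0.46), HEG1 (0.44), SLC22A15 (0.40), RAB29 (0.32) and ZRANB2 (0.29). Below it were GASK1B (-1.42), ADGRL2 (-1.39), IGF1 (-1.31), KIT (-1.13), MPEG1 (-0.97), SLC4A3 (-0.97), CD84 (-0.91), ABCA6 (-0.91), JAML (-0.76) and ENPP2 (-0.71). KDM7A, RHOQ, IGF1, KIT, MPEG1, CD84, ABCA6 and ENPP2 were called under all 19 alternatives that did not also ask for a log2 fold change of at least 1. The call was lost in 16 of the 19 for GASK1B, in 12 for PHLDA1, in 11 each for SLC22A15, RAB29 and ZRANB2, in 10 for ADGRL2, in 9 for JAML, in 8 for HEG1, in 4 each for NAB2 and RAPGEF2, and in 1 each for CDC42EP3 and SLC4A3.

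Of these 90 genes, 73 lay below the sum. For chance values shared through the DMSO libraries as the cause, counts simulated with additive effects gave 0 interaction calls in edgeR in the highest of 20 draws. The counts were drawn from the model that edgeR fits, so few false calls were likely beforehand. With 0 calls there were also no signs to compare, so the simulation cannot decide why most calls lay below 0. With a term for the 8 libraries, 81.2% lay below 0. As these held all of PRT220, the term came from other groups, so the split stays open. A limit on further rises of raised genes, biological or from the log2 scale, stays open and was not tested. Of 50 splits, the real one included, 9 gave at least 90 calls, the highest other 3392 and the lowest 0. Splits can set treated against untreated libraries, so this test, fixed beforehand, cannot decide whether chance gave the 90.

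In 8 libraries of 5 groups the RRP-named genes were far lower than in the other 16. Lower ribosome biogenesis in those cells would lower other members of that list as well, but the median log2 difference of the 24 other members was 0.024, against -3.02 for the 9 RRP-named genes. Sequence shared with RRP transcripts does not explain the 109 genes without such names that were lower by over 1 on the log2 scale, since those with transcripts in the reference shared a 31-base word with an RRP transcript 0.873 times as often as other tested genes. A candidate explanation that stays open is removal of reads before counting, by a reference for ribosomal RNA that also took in genes with such names. The median of -3.02 is what led to this idea, so removal cannot be told apart from another cause shared by those libraries. The labels name no batch, and no biological explanation other than lower ribosome biogenesis was tested.

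The retained-intron share with PRT220 lay above that with DMSO while all PRT220 libraries and 1 DMSO library belonged to the 8. With a term for those libraries the difference was 0.710 percentage points, against 0.337 without it (pooled SD 0.223). Without the term it was 0.175 when PRT220 C was left out, so its size rests in part on 1 library. The term came from other groups, where the 8 lay lower, so for PRT220 the split stays open. A biological effect of the treatment stays open as a hypothesis, since 3 libraries per group cannot give an exact p below 0.1.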

How the results depend on the processing

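The term for the 8 libraries low in RRP9, and the fits of those 8 or the other 16 alone, were chosen after seeing the data; the other alternatives were planned. The depth of 32.5e6 to 61.1e6 counts and 3 libraries per group set the limits: simulated 1.5-fold changes were recovered in 56% of cases and simulated 1.5-fold interactions in 39%. Of 1276 pairs of a named gene and a comparison, 1028 were called. Leaving aside the demand for a log2 fold change of at least 1, 848 of them kept the call under every alternative, while 180 lost it in at least 1 and 8 changed direction. The cause was not tested, except where the alternative leaves fewer libraries or asks for a larger change. The replicate letter gave no shared pattern (median residual r -0.00169, from -0.560 to 0.449 over 84 pairs of libraries with the same letter, 8 of 24 libraries closest to their own letter); with it as a block there were 3945 calls for PRT220, 5248 for GSK-LSD1, 7530 for their combination, 61 for the interaction, 294 for MS023, 6085 for MC4455 and 4840 for MC4491. Usage counts with the block were 362 for GSK-LSD1 and 291 for MS023.

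A log2 fold change of at least 1 left 305 genes for PRT220, 786 for GSK-LSD1, 1165 for their combination, 935 for the combination against PRT220, 77 against GSK-LSD1, 9 for the interaction, 18 for MS023, 1139 for MS023 with GSK-LSD1, 885 against MS023, 50 against GSK-LSD1, 405 for MC4455 and 261 for MC4491. DESeq2 gave 198 interaction genes for PRT220, 626 for MS023, 19 for the MS023 interaction and 18 for MC4455 against MC4491. No filter gave 54 interaction genes for PRT220, 1146 for MS023 with GSK-LSD1 against GSK-LSD1 and 1 for MC4455 against MC4491. The compared groups alone gave 53 interaction genes for PRT220, 0 for MS023 in edgeR, 2963 for MC4491 and 4 for MC4455 against MC4491. For MS023 the fits of all groups gave 2510 genes at an unadjusted p below 0.05 in edgeR and 626 calls in DESeq2.

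The 8 libraries held 1 of DMSO and 1 of each combination, and the 16 held 1 of MS023. Within the 8 there were 1953 genes for PRT220, 3167 for its combination with GSK-LSD1 against PRT220, 6 for MS023 and 3536 for its combination against MS023. The counts there for the PRT220 combination (3758) and the MS023 combination (2890) compare 1 library with 1 of DMSO, so the spread comes wholly from other groups and they tell nothing on how firm the calls are. Within the 16 there were 9 for MS023, 3359 for MS023 with GSK-LSD1 against MS023, 2 for the MS023 interaction and 1 for MC4455 against MC4491. The term gave 599 for MS023 and 2945 for MS023 with GSK-LSD1 against GSK-LSD1. Some genes changed direction. For PRT220, the log2 fold change of RRP9 became 0.46 within the 8 and 0.43 with the term, that of MT-CYB 0.18 and 0.30, and that of MT-ND6 0.094 with the term. For the combination against PRT220, RRP9 became -0.31 and -0.38, MT-CYB -0.39 and -0.42, MT-ND5 -0.21 and -0.34, MT-ND6 -0.21 and -0.23, and RRP12 -0.012 with the term.

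Leaving out 1 library each, the counts ran from 1662 to 2033 for the PRT220 combination against GSK-LSD1 (main 2553, lowest without its replicate B), 27 to 98 for the PRT220 interaction (main 90, lowest without PRT220 C, 50 without PRT220 B, 53 without DMSO B, 41, 39 and 48 without GSK-LSD1 A, B and C, and 52, 45 and 49 without replicates A, B and C of the combination), 185 to 328 for MS023 (main 375, lowest without MS023 A, 194 without DMSO B, 193 without MS023 B), 465 to 1818 for MS023 with GSK-LSD1 against GSK-LSD1 (main 1808, lowest without GSK-LSD1 B, 695 without GSK-LSD1 A, 1192 without GSK-LSD1 C, and 1077 and 580 without replicates A and C of the combination), 0 to 1 for the MS023 interaction (1 without GSK-LSD1 A or without MS023 C) and 0 to 29 for MC4455 against MC4491 (highest without MC4455 B). Usage counts ran from 334 to 465 for GSK-LSD1, 314 to 407 for MS023, 899 to 1430 for MS023 with GSK-LSD1, 1017 to 1392 for MC4455 and 912 to 1072 for MC4491, with the lowest without GSK-LSD1 A, MS023 A, replicate C of that combination, MC4455 B and MC4491 A. Other libraries that moved a usage count were DMSO C (364), GSK-LSD1 B (391) and GSK-LSD1 C (375) for GSK-LSD1, DMSO A (332) and DMSO B (322) for MS023, replicate A (997) for MS023 with GSK-LSD1, and DMSO C (1097) and MC4455 C (1078) for MC4455. The retained-intron difference of MS023 (0.141 percentage points) ran from -0.104, without MS023 B, to 0.314, without MS023 C. That of PRT220 ran from 0.175, without PRT220 C, to 0.483, that of its combination from 0.491, without its replicate A, to 0.951, and that of the MS023 combination from 0.366, without its replicate C, to 0.888. Without 1 DMSO library the correlation rose from 0.315 to between 0.415 and 0.450 for PRT220 and GSK-LSD1, and lay between 0.485 and 0.532 for PRT220 and MS023, 0.420 and 0.465 for PRT220 and the MS023 combination, 0.470 and 0.543 for PRT220 and MC4455, 0.443 and 0.485 for PRT220 and MC4491, 0.440 and 0.474 for GSK-LSD1 and MS023, 0.433 and 0.480 for the PRT220 combination and MS023, and 0.506 and 0.574 for MS023 and MC4455.

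For transcript usage diffSpliceDGE gave 484 genes for PRT220, 373 for GSK-LSD1, 630 for their combination, 487 for MS023 with GSK-LSD1, 465 for MC4455 and 387 for MC4491. The 8 libraries, with 1 of DMSO, gave 840 for PRT220 and 75 for MS023, and the 16 gave 1374 for the PRT220 combination and, with 1 library of it, 214 for MS023. The 8 gave 287 for the PRT220 combination and 93 for the MS023 combination, again 1 library against 1, so these counts tell nothing on how firm the calls are. A filter of 1 CPM gave 348 for GSK-LSD1 and 308 for MS023. The retained-intron difference with the term was 0.710 for PRT220, 0.0548 for GSK-LSD1 and 0.575 for MC4491, and over genes with both transcript types it was 0.343 for GSK-LSD1, 1.42 for MC4455 and 1.10 for MC4491.

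Of the lists called by camera, an estimated correlation left 1 of 9 for PRT220, 2 of 8 for GSK-LSD1, 3 of 11 for their combination, 3 of 7 for that against PRT220, 2 of 10 for MS023 with GSK-LSD1 and 2 of 11 for that against MS023. It left 0 of 8 for the PRT220 combination against GSK-LSD1, 0 of 6 for its interaction, 0 of 10 for MS023, 0 of 7 for MS023 with GSK-LSD1 against GSK-LSD1, 0 of 7 for the MS023 interaction, 0 of 11 for MC4455, 0 of 13 for MC4491 and 0 of 3 for MC4455 against MC4491. Fry's directional test called 17 lists for GSK-LSD1, 21 for the PRT220 combination, 18 for that against PRT220, 3 for the interaction, 1 for MS023, 17 for MS023 with GSK-LSD1, 20 for that against MS023, 0 for the MS023 interaction, 18 for MC4455 and 0 for MC4455 against MC4491. Its mixed test called 24 lists for PRT220, GSK-LSD1, both combinations against DMSO and against the methyltransferase inhibitor, MC4455 and MC4491, 20 for both combinations against GSK-LSD1, and 2 for the MS023 interaction. With the term, the BCL2 family and MAPK lists were no longer called for MC4491 (camera adjusted p = 0.055 and 0.0898).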

Other observations

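The set of immediate-early genes, the fits of the 16 and the 8 libraries, and the splits of the libraries for transcript usage were chosen after the values were seen, while the splits for gene calls were chosen before theirs. Immediate-early genes respond within minutes to a stimulus or to handling. The 15 tested include KLF2, RHOB and DUSP1, named above for their falls. Of the 15, 12 fell with each of MC4455 and MC4491 and 1 rose with MC4455, with median log2 fold changes of -0.88 and -0.91. KLF2 was at 13.2 CPM with DMSO, 4.16 with MC4455 and 4.37 with MC4491, DUSP1 at 21.2, 8.94 and 9.23, and EGR1 at 79.6, 43.3 and 46.1 CPM (means, n = 3). Fewer of the set fell with the other treatments: 4 with PRT220, 6 with GSK-LSD1, 8 with their combination, 0 with MS023, and 6, with 2 rises, with MS023 and GSK-LSD1, with medians of -0.22, -0.21, -0.45, -0.03 and -0.22. Neither the set as a list nor treatment differences were tested.

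The libraries of each pair of groups were also regrouped in all other ways. With 3 against 3 libraries the 10 splits are too few for a share under 0.05, and in each comparison that follows, except where stated, 1 of the 10, the real one, gave as many calls. PRT220 against DMSO gave 4139 genes against at most 20 in another split, GSK-LSD1 5419 against 1, and their combination 7735 against 0. The combination against PRT220 gave 6350 against 2, and against GSK-LSD1 2553 against 0. MS023 with GSK-LSD1 against DMSO gave 8054 against 1, and against GSK-LSD1 1808 against 1. MC4455 gave 6264 against 1 and MC4491 5112 against 210. MS023 gave 375 against 76, in a split with DMSO A, DMSO B and MS023 B on 1 side, which follows the split of the libraries by RRP9; within the 16 and the 8 libraries, which held 1 of MS023 and 1 of DMSO respectively, there were 9 and 6 calls. MS023 with GSK-LSD1 against MS023 gave 6659 against 656, in the split that follows RRP9 as well, with 3359 and 3536 calls within the 16 and the 8. MC4455 against MC4491 gave 0 genes in edgeR, so that 10 of 10 splits gave as many, which any count must against 0 and which says nothing on chance, with 30 in the highest other, 780 at an unadjusted p below 0.05 and 18 in DESeq2.

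For the interaction of MS023 with GSK-LSD1, with 0 genes called in edgeR, 1356 at an unadjusted p below 0.05 and 19 in DESeq2, 50 of 50 splits gave as many, as any count must against 0. The highest other gave 5096 and the lowest 0. Why counts varied was not tested, and with a real count of 0 this says nothing on chance. For transcript usage the other splits gave more calls than for gene levels. The real count and the highest other were 1861 and 531 with PRT220, 591 and 325 with GSK-LSD1, 2243 and 344 with their combination, 1532 and 420 with MS023 and GSK-LSD1, 1682 and 367 with MC4455, and 1417 and 508 with MC4491, each with 1 of 10 splits as large. With MS023 the count was 502, and 2 of 10 splits gave as many, the other with 544.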
